A study of Mus musculus with 24 samples.

How the data were processed

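RNA levels were measured in primary vascular smooth muscle cells of the mouse carotid artery on 24 Illumina bead arrays, each holding 25697 probes. Per the labels' protocols, PMCA4b or vector DNA was brought into knockout cells by electroporation, and all cells were synchronized, stimulated with serum and platelet-derived growth factor BB, and collected near the G1/S boundary. RNA was extracted with a PicoPure kit and biotin-labelled cRNA was made with an Illumina TotalPrep kit, per the labels' protocols. The labels give 5 arrays each to wild type, knockout, knockout with PMCA4b and knockout with vector A, and 4 arrays to knockout with vector B.

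The deposited intensity table holds one background-subtracted bead intensity per probe and array, not normalized between arrays. Between 28.28% and 30.86% of its values lie below 0 on each array. The deposited detection p-values move in steps that 798 negative control beads would give. A further deposited table holds the authors' log2 values. Their ranks within an array equal those of the same array's intensities (Spearman 1, against at most 0.961 for any other array), and all columns share the same quantiles, with a median of 6.24, so they are log2 values with quantile normalization. The scanner software, the background method and the exact normalization steps are not given in the sources used here.

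The intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which infers the background from the detection p-values, adds an offset of 16 and applies quantile normalization. Tables were handled with data.table (version 1.17.8), and figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Probes with a detection p under 0.01 on at least 4 arrays were kept, which left 11139 probes. Gene names came from the platform annotation, which gives 23978 probes a single gene and leaves 1719 unnamed. Of the kept probes, 10504 had a name and 635 had none. The named probe with the highest mean over all arrays stood for its gene, which gave 7675 genes, of which 2039 had several kept probes. Between 23 and 206 genes per comparison had called probes that moved in opposite directions. A mouse gene table of assembly GRCm38.p6 served only for names and for which genes lie next to each other.

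A linear model with a mean for each of the 5 groups was fitted to all 24 arrays with limma, which leaves 19 residual degrees of freedom. Moderated two-sided tests were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. The comparisons were knockout against wild type, PMCA4b against the average of both vector means, PMCA4b against each vector, vector B against vector A, and the vector average against knockout. A probe undetected on an array has only an upper bound there. Where some or all arrays of the dimmer side are undetected, the fold is given as "at least N-fold", from the bright group's mean against the mean of, per array, the higher of the probe's own value and the lowest value among detected probes, which lay between 6.16 and 6.57 on the log2 scale. The top of the scale was 16.016 on each array, and folds of a gene near it are also given as at least. The counts of changed genes and the list medians use the fitted values.

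The 23 gene lists were G1/S and DNA replication, G2/M and mitosis, cell cycle inhibitors, calcium transport, calcineurin and calmodulin signalling, immediate early and serum response, contractile smooth muscle, extracellular matrix, growth factors and their receptors, the RGS family, interferon response, cytokines and NF-kB, endoplasmic reticulum stress, cholesterol and lipid synthesis, glycolysis and hypoxia, fatty acid oxidation, ribosomal proteins, and markers of fibroblasts, endothelium, leukocytes, adipocytes, chondrocytes, and a joint list for Schwann, epithelial and skeletal muscle cells. The 18 lists with at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, against the other genes, and adjusted over lists. Camera with an estimated correlation and fry, which asks only whether a list's genes move on balance in 1 direction, were alternatives. Genes called "adjusted over the list alone" had their p-values adjusted within the list.

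The genes named were chosen by a rule. It took Atp2b1 to Atp2b4 and Rgs16 everywhere, the last from memory of the study. It took the 8 largest called changes in each direction for knockout against wild type and for PMCA4b against vector, and 4 for other comparisons, among genes whose groups did not overlap. It added up to 3 genes per list with the smallest adjusted p, and the 10 genes with the largest opposed change. Genes without a regular name were passed over, and not every gene of the rule is printed. Groups, comparisons, lists, the rule and all alternatives except those said to be chosen later were fixed before the data were examined. Alternatives covered the background correction, offset, scaling, the authors' values, the filter, the choice of probe, array weights, the variance prior, a fold minimum of 1.5, the arrays in the fit, pooling of the vectors, a replicate block and leaving out single arrays. The chip as a block was planned for the case that the file names the chips, which it does not, so it was not run.

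The model fit and its tests were tried on simulated normalized values. These had each gene's own mean and residual SD and independent normal noise, with 50 genes for each size of change. Normalization, the filter and the choice of probe were not part of this. Far fewer genes were changed than were called in the data, so recovery and false calls may differ there. For knockout against wild type, 28 of 50 genes with a log2 change of 0.25 were recovered, 44 of 50 at 0.5, 49 of 50 at 1 and 50 of 50 at 2, with 9 false calls among 7447 unchanged genes. For PMCA4b against vector the numbers were 29, 46, 50 and 50 of 50, with 9 false calls among 7444. At 0.25, 11 of 50 were recovered for PMCA4b against vector B and 14 of 50 for vector B against vector A. As a check of the labels, which call all cells male, Eif2s3y of the Y chromosome was detected on 24 of 24 arrays, Uty on 23 and Kdm5d on 13, the last on 0 of 5 with PMCA4b and 1 of 5 in knockout cells, and Xist on 0 of 24.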

Results

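Vascular smooth muscle cells are the contractile cells of the arterial wall, and in culture they can divide. PMCA4, the product of Atp2b4, is a plasma membrane pump that moves calcium out of the cell, and PMCA4b is one of its splice forms. Gene expression near the entry into S phase was compared in wild-type cells (5 arrays), PMCA4 knockout cells (5 arrays), and knockout cells electroporated with PMCA4b DNA (5 arrays) or with vector DNA. The vector cells came as vector A (5 arrays) and vector B (4 arrays), and the labels do not say how these differ. Between 9496 and 10406 of the 25697 probes were detected on each array (36.95% to 40.49%). The median SD within groups was 0.111 on the log2 scale, and the number of arrays limits the precision. Whether replicates came from separate cultures or animals is not given, so p-values measure the spread between these samples, which may be technical.

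The groups lay far apart and their arrays close together. The first principal component held 48.4% of the variance and separated both vector groups from the other 3 groups, and the second held 26.5% and separated the PMCA4b cells.

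**Figure D1:**
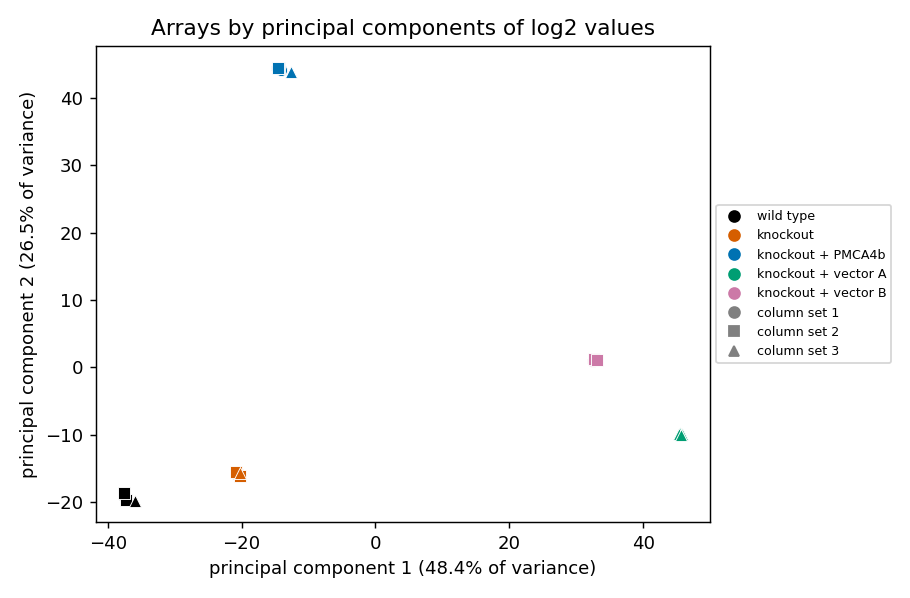
Each point is an array, placed by its first and second principal components over all genes tested, coloured by group and shaped by its set of 8 neighbouring columns in the deposited file. Vector A arrays lie between 45.3 and 45.8 on the first component and vector B arrays between 32.5 and 33.1, while all wild-type, knockout and PMCA4b arrays lie below 0.

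The targeted gene Atp2b4 had 1 probe above background. It read 6.81 ± 0.209 (SD, n = 5) in wild-type cells and 6.84 ± 0.181 (SD, n = 5) in knockout cells, a log2 difference of 0.03 (SE 0.17, limma adjusted p = 0.881, exact two-sided permutation p = 0.802, where 0.00794 is the smallest p the design allows). It read 6.73 ± 0.513 (SD, n = 5) with PMCA4b, 6.68 ± 0.161 (SD, n = 5) with vector A and 6.72 ± 0.233 (SD, n = 4) with vector B, close to the detection limit. The log2 difference of PMCA4b from vector was 0.03 (SE 0.15, limma adjusted p = 0.88), and its sign turns with the scaling of the arrays. Where this probe lies relative to the deleted part, and from which species the PMCA4b DNA came, is not given in the sources used here, so the probe checks neither the deletion nor the return of the pump. The other Atp2b4 probes and all probes of Atp2b2 and Atp2b3 were detected on 0 of 24 arrays. Atp2b1, the widely expressed sister pump, read 8.48 ± 0.0856 (SD, n = 5) in wild type and 8.97 ± 0.134 (SD, n = 5) in knockout cells, 1.40-fold higher (limma adjusted p = 8.85e-07).

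Knockout against wild type asks which genes differ in cells without PMCA4, and differences between single cultures enter as well. Rgs16, a regulator that shuts off G protein signalling, rose at least 18.95-fold, from 6.31 ± 0.354 (SD, n = 5) to 10.7 ± 0.0905 (SD, n = 5), and was detected on 2 of 5 wild-type arrays (limma adjusted p = 5.46e-19). Grb10, an adaptor of insulin and insulin-like growth factor receptors, was at least 51.8-fold higher in knockout cells (12.1 ± 0.0857, SD, n = 5) and undetected in wild type. It was also undetected with PMCA4b, vector A and vector B. Vector cells are knockout cells too, so this rise is not common to all cells without PMCA4. Thy1, a surface glycoprotein of fibroblasts, rose 41.8-fold, and Esm1, a secreted proteoglycan also called endocan, rose 32.0-fold. Serpinf1, a secreted inhibitor of vessel growth, rose at least 76.86-fold and was detected on 1 of 5 wild-type arrays. Igfbp6, which binds insulin-like growth factors, the actin-severing protein gelsolin (Gsn) and podoplanin (Pdpn) were undetected in wild type and at least 15.9-fold, 15.1-fold and 13.1-fold higher in knockout cells. Hspb7, a small heat shock protein, rose at least 23.13-fold, with 2 of 5 wild-type arrays detected.

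Lower in knockout cells were Gdnf, a neurotrophic factor (at least 8.92-fold, detected on 1 of 5 knockout arrays), the homeobox factor Dlx1 (8.37-fold), Plac8 (6.86-fold) and Tuft1 (6.85-fold). Inmt, a methyltransferase, was detected on all 5 wild-type arrays at 8.295 ± 0.110 (SD, n = 5) and on no array of any knockout-derived group, at least 3.68-fold lower in knockout cells. Slc25a45, a member of the mitochondrial carrier family, the interferon-inducible GTPase Gvin1 and the death receptor Tnfrsf21 were undetected in knockout cells and at least 5.88-fold, 5.15-fold and 4.93-fold lower. The limma adjusted p of these named genes was at most 4.25e-16, and the knockout and wild-type arrays of each did not overlap.

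Genes of cell division fell in knockout cells. Of 31 measured genes of G2/M and mitosis, 29 fell and 0 rose (29 fell adjusted over the list alone; camera adjusted p = 8.55e-11). Of 47 measured genes of G1/S and DNA replication, 32 fell and 6 rose (34 and 6 adjusted over the list alone; camera adjusted p = 0.000345). The mitotic kinase Plk1 fell 1.71-fold, Kif23, a motor of cytokinesis, 1.98-fold, the transcription factor E2f2 3.73-fold and Mybl2, a transcription factor of proliferating cells, 3.31-fold. Cdkn1a, the cell cycle inhibitor p21, rose 2.52-fold. The list of cell cycle inhibitors as a whole was not called, with 11 of 25 higher and 8 lower (camera adjusted p = 0.188).

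Contractile and matrix genes rose. Of 14 measured contractile smooth muscle genes, 11 rose and 0 fell (11 adjusted over the list alone; camera adjusted p = 2.25e-05). Smooth muscle actin, Acta2, rose at least 2.64-fold to 15.96 ± 0.0328 (SD, n = 5), close to the top of the scale, with log2 changes from 1.40 to 2.48 over its 4 probes, and Mustn1, a muscle regeneration gene, rose 4.40-fold. Actg2, the enteric smooth muscle actin, was undetected in wild type and at least 1.54-fold higher. Of 32 extracellular matrix genes, 23 rose and 5 fell (23 and 5 adjusted over the list alone; camera adjusted p = 2.68e-07). The basement membrane collagens Col4a1 and Col4a2 rose 2.77-fold and 3.22-fold. Decorin (Dcn), a small collagen-binding proteoglycan, was undetected in wild type and at least 10.5-fold higher. Of 9 fibroblast markers, 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 2.56e-05), among them Thy1, Dcn, which stands in both lists, and the matrix protein Dpt (at least 6.33-fold).

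Of 23 interferon response genes, 17 fell and 4 rose (17 and 4 adjusted over the list alone; camera adjusted p = 0.000441). The deubiquitinating enzyme Usp18 and the GTPase Igtp were undetected in knockout cells and at least 2.96-fold and 2.34-fold lower. Of 26 immediate early genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.0445). Dusp4, a phosphatase of MAP kinases, rose 3.21-fold and Ier3 1.65-fold, while the transcription factor Egr1 fell 1.77-fold.

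The other lists were not called (camera adjusted p from 0.102 to 0.691). Among calcium transport genes 6 of 20 were higher and 3 lower. Among calcineurin and calmodulin genes 9 of 27 were higher and 8 lower, with Rcan2, a calcineurin regulator, 2.94-fold lower. Of 6 measured RGS genes 1 was higher and 3 lower, Rgs17 by at least 5.61-fold, detected on 2 of 5 knockout arrays. Higher and lower genes numbered 14 and 7 of 32 for growth factors, 12 and 7 of 23 for cytokines, and 6 and 13 of 27 for endoplasmic reticulum stress. They numbered 11 and 4 of 24 for cholesterol synthesis, 6 and 9 of 25 for glycolysis, 9 and 6 of 21 for fatty acid oxidation, and 4 and 5 of 27 for ribosomal proteins. Counts adjusted over the list alone were the same, except for 9 lower inhibitors, 10 lower glycolysis genes, and 2 higher and 3 lower ribosomal proteins. The RGS genes had a median log2 of -0.39 and a mean of 0.06. Too few genes for a test were measured of endothelial (2 of 3 higher, 1 lower), leukocyte (0 of 1 higher, 1 lower), adipocyte (2 of 3 higher, 0 lower) and chondrocyte markers (2 of 4 higher, 1 lower), and of the Schwann, epithelial and skeletal muscle list (2 of 3 higher, 0 lower). Adjusted over the list alone these were the same, except for 3 higher adipocyte markers. Of the adipocyte calls, that of Plin4 (log2 0.2309) was lost under several alternatives, such as a fit on these groups alone (limma adjusted p = 0.0943).

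Over all genes 4428 of 7675 were called, 2038 higher and 2390 lower in knockout cells, and 1259 of them by at least 1.5-fold. At least 2-fold changes numbered 318 higher and 192 lower. For 3019 called genes the arrays of both groups did not overlap, against 0.794% of genes by chance. The deposited columns fall into 3 sets of 8, presumed chips, and within single sets, with fewer arrays, 2743, 2790 and 2216 genes were called (the last with 1 array per group and the spread of vector A), against 4593 with the set as a block. All 7 list calls held with an estimated correlation. Of 100 splits of these 10 arrays, 7, the real one included, gave 7 or more called lists. Such splits can keep part of the real difference, so this count does not decide the list calls.

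**Figure D2:**
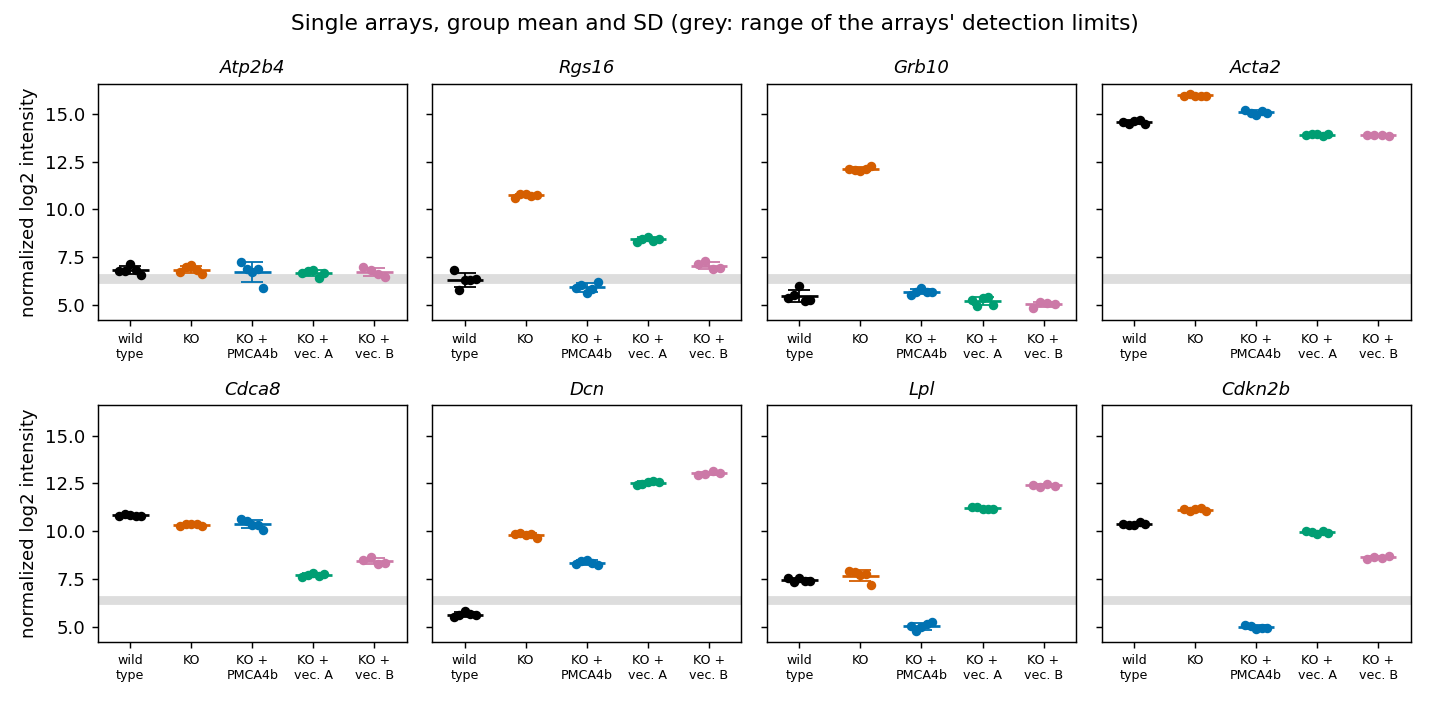
Normalized log2 intensity of 8 genes on every array, with group means and SD as error bars, and the range of the arrays' detection limits in grey (6.16 to 6.57). Grb10 is above the limits in knockout cells alone, Cdkn2b is below them with PMCA4b alone, and Dcn is below them in wild type alone.

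PMCA4b against vector asks what PMCA4b DNA changed in knockout cells, compared with vector DNA. Lpl, the lipoprotein lipase that releases fatty acids, read 5.03 ± 0.178 (SD, n = 5) with PMCA4b, below detection, against 11.2 ± 0.0613 (SD, n = 5) with vector A and 12.4 ± 0.0679 (SD, n = 4) with vector B, at least 39.5-fold lower (limma adjusted p = 1.4e-25). Ogn, a small matrix proteoglycan, fell 43.4-fold, and the copper carrier ceruloplasmin (Cp) 22.9-fold. The actin-severing protein Scin, the lipid droplet protein Plin4 and the transcription cofactor Lmo2 were undetected with PMCA4b and at least 13.5-fold, 10.2-fold and 8.79-fold lower. Emb, a cell adhesion glycoprotein, and Igfbp3, a carrier of insulin-like growth factors, fell at least 29.41-fold and 21.93-fold, each detected on 1 of 5 PMCA4b arrays. Rgs16 was undetected with PMCA4b, at 5.92 ± 0.221 (SD, n = 5), and at least 2.39-fold lower than with vector.

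Higher with PMCA4b were Crabp1, a retinoic acid carrier, at 10.3 ± 0.0867 (SD, n = 5) and at least 9.43-fold above vector, where it was detected on 4 of 9 arrays, and Otud7a (at least 7.64-fold, 4 of 9), Mmp23 (at least 6.21-fold, 1 of 9) and the desmosome protein Pkp1 (at least 7.18-fold, 2 of 9). Fxyd6, a modulator of the sodium pump, the adhesion molecule Ncam1, the protease Ctsw and Akr1c12, an aldo-keto reductase, were undetected with vector and at least 8.57-fold, 6.28-fold, 5.71-fold and 3.62-fold higher. The limma adjusted p of these named genes was at most 4.06e-13, and PMCA4b and vector arrays of each did not overlap.

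Genes of cell division were higher with PMCA4b than with vector, where they had fallen below knockout cells. Of 47 genes of G1/S and DNA replication, 42 rose and 3 fell (42 and 3 adjusted over the list alone; camera adjusted p = 2.57e-10), and of 31 genes of G2/M and mitosis, 29 rose and 0 fell (29 adjusted over the list alone; camera adjusted p = 2.96e-10). Cdca7 rose 3.89-fold, the helicase subunit Mcm7 3.12-fold, Mybl2 3.76-fold, the mitotic kinase Aurka 3.05-fold and Cdca8, a subunit of the chromosomal passenger complex, 4.95-fold. Beside these lists stands Cdkn2b, the inhibitor p15 of the G1 kinases, which was undetected on all 5 PMCA4b arrays (4.97 ± 0.0999, SD, n = 5) and detected on all 19 other arrays, and was at least 6.94-fold lower than with vector. Both probes of its neighbour Cdkn2a, named after its values were seen, were also detected on 0 of 5 PMCA4b arrays and on all 19 others. The list of inhibitors was not called, with 7 of 25 higher and 14 lower (camera adjusted p = 0.14).

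Lipid and matrix genes fell. Of 24 genes of cholesterol and lipid synthesis, 23 fell and 0 rose (23 adjusted over the list alone; camera adjusted p = 1.25e-07), with the sterol enzymes Msmo1 and Hmgcs1 4.05-fold and 2.93-fold lower. Of 21 genes of fatty acid oxidation, 14 fell and 3 rose (14 and 3 adjusted over the list alone; camera adjusted p = 0.0153), with the carnitine transferase Cpt2 2.87-fold and the thioesterase Acot1 3.32-fold lower. Both lists rose with vector against knockout, with a mean log2 of 0.621 for lipid synthesis and 0.421 for fatty acid oxidation. For PMCA4b against vector the means were -0.994 and -0.462. Acot1 read 8.511 with PMCA4b and 7.955 in knockout cells. Of 32 matrix genes, 22 fell and 5 rose (22 and 5 adjusted over the list alone; camera adjusted p = 0.000468), with Dcn 21.4-fold and Mgp, an inhibitor of calcification, 13.1-fold lower. The fibroblast markers, with 7 of 9 lower and 2 higher, were not called (camera adjusted p = 0.0772). Pdgfra, a receptor of platelet-derived growth factors, was undetected with PMCA4b and at least 3.29-fold lower.

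Of 26 immediate early genes, 16 fell and 7 rose (16 and 7 adjusted over the list alone; camera adjusted p = 0.0312). The mean log2 of this list was -0.704, against 0.521 for vector against knockout, where it was not called (camera adjusted p = 0.0705). Fos, a subunit of the AP-1 transcription factor, was undetected with PMCA4b and at least 8.24-fold lower, and Ier3 and the phosphatase Dusp1 fell 7.72-fold and 6.81-fold. Of 23 interferon response genes, 16 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 0.012), Ifit3 by 7.53-fold. Of 32 growth factors and receptors, 20 fell and 8 rose (20 and 8 adjusted over the list alone; camera adjusted p = 0.026), Igfbp5 by at least 14.4-fold, but with an estimated correlation the adjusted p was 0.0737. Of 27 endoplasmic reticulum stress genes, 16 fell and 4 rose (16 and 4 adjusted over the list alone; camera adjusted p = 0.0312), and with an estimated correlation the adjusted p was 0.114. Among its members Sel1l, of the degradation machinery, fell 2.47-fold, and Phgdh, of serine synthesis, rose 3.15-fold.

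Lists not called were calcium transport, with 9 of 20 higher and 9 lower, calcineurin signalling with 9 and 14 of 27, contractile genes with 8 and 3 of 14, and the RGS family with 2 and 2 of 6. Cytokines had 6 higher and 12 lower of 23, glycolysis 7 and 15 of 25, and ribosomal proteins 16 and 5 of 27 (camera adjusted p from 0.0667 to 0.852 over these lists, with the same counts adjusted over the list alone). For calcium transport and the RGS family the median log2 (0.02 for both) and the mean (-0.16 and -0.14) differ in sign. Of the lists too short for a test, adipocyte markers were lower (3 of 3) and endothelial markers higher (3 of 3). The leukocyte marker Cd14 was lower (1 of 1, log2 -0.142), a call lost under several alternatives, such as pooled vectors (limma adjusted p = 0.333). Against vector A alone it was not called (log2 0.113). Chondrocyte markers were 1 higher and 2 lower of 4, and the Schwann, epithelial and skeletal muscle list 2 higher and 1 lower of 3. All these short lists had the same counts adjusted over the list alone. In the calcium, calcineurin and contractile lists the calcium release channel Itpr2 fell 3.19-fold, Rcan2 fell at least 4.78-fold and was detected on 1 of 5 PMCA4b arrays, and Acta2 rose at least 2.27-fold, with log2 changes from 1.18 to 2.78 over its 4 probes.

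Over all genes 6051 of 7675 were called, 2942 higher and 3109 lower with PMCA4b, and 2825 of them by at least 1.5-fold. At least 2-fold changes numbered 491 higher and 794 lower. For 3939 called genes the 5 PMCA4b arrays did not overlap the 9 vector arrays, against 0.0999% of genes by chance. The vector groups differ from each other in the cell division lists, and the number of calls was 6054 with the column set as a block.

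**Figure D3:**
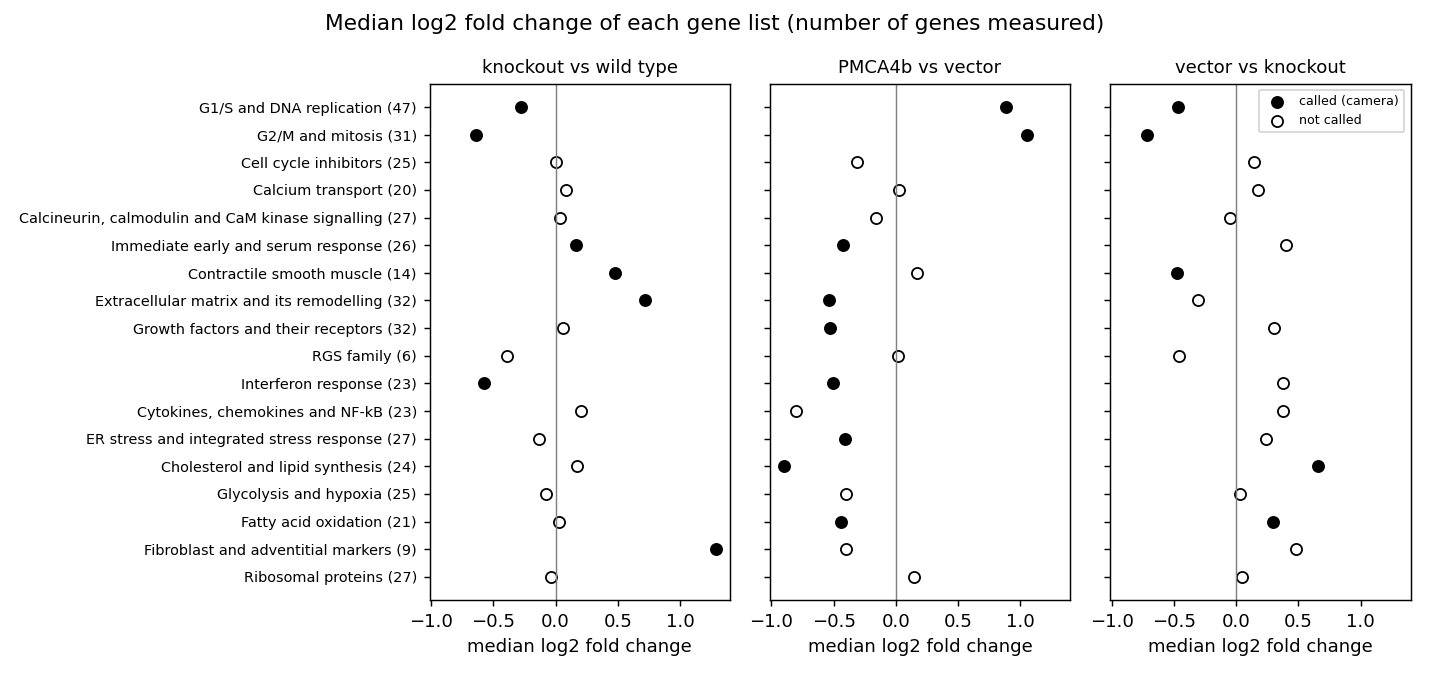
Median log2 fold change of the 18 tested gene lists in 3 comparisons, filled where camera called the list, with the number of genes measured in brackets. The list of G2/M and mitosis has a median of -0.635 for knockout against wild type, 1.05 for PMCA4b against vector and -0.713 for vector against knockout, and -0.635, 1.04 and -0.675 where undetected groups are set at their bound.

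Taken against each vector, PMCA4b cells differed at 6047 genes from vector A (2976 higher and 3071 lower) and at 5541 genes from vector B (2640 higher and 2901 lower). Rgs16 was at least 3.83-fold lower than with vector A and at least 1.49-fold lower than with vector B. Egfl7, a secreted protein of vessels, and Crabp1 were undetected with vector A and at least 7.54-fold and 15.8-fold higher with PMCA4b. Against vector B, Uchl1, a ubiquitin hydrolase detected on 2 of 4 vector B arrays, rose at least 7.38-fold, and the chemokine Cxcl15 and the matrix protein Thbs2 were undetected with PMCA4b and at least 14.5-fold and 18.7-fold lower. Of 31 mitosis genes, 31 were higher than with vector A and 25 higher and 1 lower than with vector B (31, and 25 and 1, adjusted over the list alone; camera adjusted p = 2.12e-11 and 1.36e-08). Of 24 cholesterol genes, 21 were lower and 1 higher than with vector A, and 24 were lower than with vector B (21 and 1, and 24, adjusted over the list alone; camera adjusted p = 9.81e-06 and 9.67e-09). Calls at least 1.5-fold numbered 3297 and 2567, and non-overlapping called genes 5149 and 4702, against 0.794% and 1.59% by chance. Each comparison called 9 lists. Of 47 replication genes 42 were higher and 2 lower than with vector A, and 37 higher and 2 lower than with vector B (42 and 2, and 38 and 2, adjusted over the list alone). Of 32 matrix genes 20 were lower and 5 higher than with vector A, and 22 lower and 4 higher than with vector B (20 and 5, and 22 and 5, adjusted over the list alone). The interferon list was called against vector A, with 16 of 23 lower and 1 higher (16 and 1 adjusted over the list alone; camera adjusted p = 0.00244), and the cytokine list against vector B, with 13 of 23 lower and 6 higher (13 and 6 adjusted over the list alone; camera adjusted p = 0.0244). The growth factor list lost its call with an estimated correlation in both (adjusted p = 0.0563 and 0.0829), as did ribosomal proteins against vector A (17 of 27 higher and 4 lower, the same adjusted over the list alone; adjusted p = 0.0561) and endoplasmic reticulum stress against vector B (adjusted p = 0.0639). Against vector A, a fit on these 10 arrays alone called 7 lists and 10 of 100 splits gave as many, and the immediate early call (camera adjusted p = 0.0402) was lost both with the replicate number and with the column set as a block (adjusted p = 0.0501 with each; from 0.00877 to 0.0501 over its camera alternatives).

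Vector B against vector A asks whether both can serve as a single control. Tril, a Toll-like receptor accessory, and Plvap, a protein of endothelial fenestrae, read 9.79 ± 0.122 (SD, n = 4) and 9.04 ± 0.110 (SD, n = 4) in vector B, were undetected in vector A, and were at least 10.8-fold and 6.45-fold higher. The zinc finger factor Tshz3 and Egfl7 were likewise at least 6.71-fold and 6.06-fold higher. Dlk1, a Notch-like inhibitor of fat cell formation, was undetected in vector B and at least 8.47-fold lower, and Esm1, Lmo2 and the microfibril protein Mfap5 fell 5.74-fold, 4.98-fold and 4.79-fold. Of 31 mitosis genes, 29 were higher and 0 lower in vector B (29 adjusted over the list alone; camera adjusted p = 6.76e-11), and of 47 replication genes, 37 were higher and 2 lower (39 and 3 adjusted over the list alone; camera adjusted p = 1.17e-10). The replication kinase subunit Dbf4 was 3.55-fold and Cdc20, an activator of mitotic exit, 2.01-fold higher. Of 23 interferon genes, 14 were lower and 3 higher (15 and 3 adjusted over the list alone; camera adjusted p = 0.000832), Ifit3 by 3.30-fold. Of 23 cytokine genes, 17 were higher and 3 lower (17 and 3 adjusted over the list alone; camera adjusted p = 0.000857), with the alarmin Il33 4.51-fold higher. In all 4099 genes were called, 2142 higher and 1957 lower in vector B, 912 of them by at least 1.5-fold and 238 by at least 2-fold. For 3393 of them the arrays did not overlap, against 1.59% by chance. All vector A arrays lie in 1 column set and all vector B arrays in the other 2. With the set as a block 3148 genes were called, and 2786 of the 4099 were among them. As many called lists (4) came from 32 of 100 splits of these arrays.

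Vector against knockout sets knockout cells electroporated with vector DNA against knockout cells not given DNA. Electroporation, the DNA and separate culture cannot be told apart in it. Upk1b, a tetraspanin of the urothelium, was undetected in knockout cells and at least 29.2-fold higher with vector, at 11.9 ± 0.0779 (SD, n = 5) in vector A and 10.7 ± 0.198 (SD, n = 4) in vector B. The ferritin receptor Scara5 (at least 47.99-fold, detected on 3 of 5 knockout arrays) and the matrix protease Mmp3 (50.1-fold) rose, and Igfbp5 was at least 15.1-fold higher. Grb10 was undetected in all vector arrays and at least 54.97-fold lower, the growth factor Fgf10 at least 22.5-fold, Mustn1 at least 17.6-fold and the contractile protein Tagln at least 13.8-fold lower. Rgs16 fell 7.93-fold and Atp2b1 rose 2.09-fold (limma adjusted p = 4.12e-17 and 4.56e-14).

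Genes of cell division also fell with vector, 29 of 31 in mitosis with 0 higher (29 adjusted over the list alone; camera adjusted p = 6.86e-09) and 33 of 47 in replication with 5 higher (34 and 5 adjusted over the list alone; camera adjusted p = 2.08e-05), Cdca8 by 4.80-fold and the single-strand DNA binding subunit Rpa2 by 3.36-fold. Of 14 contractile genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00195), Acta2 by at least 4.19-fold from near the top of the scale. Of 24 cholesterol genes, 20 rose and 0 fell (20 adjusted over the list alone; camera adjusted p = 2.23e-05), with the sterol demethylase Cyp51 3.07-fold and Hmgcs1 1.89-fold higher. Of 21 fatty acid oxidation genes, 14 rose and 4 fell (14 and 4 adjusted over the list alone; camera adjusted p = 0.0302), Acot1 by 4.88-fold. In all 5708 genes were called, 3039 higher and 2669 lower with vector, 2301 of them by at least 1.5-fold and 932 by at least 2-fold. For 3335 called genes the arrays did not overlap, against 0.0999% by chance. The 5 list calls held with an estimated correlation. As many came from 9 of 100 splits of these arrays, which can keep part of the real difference.

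The last comparison asks whether PMCA4b moved the genes that changed in knockout cells the opposite way. Cell division genes, which fell in knockout cells, rose with PMCA4b, and matrix genes, which rose, fell, while interferon genes fell in both comparisons. Against vector B alone the interferon list was not called (camera adjusted p = 0.065). The 10 genes with the largest opposed changes all rose in knockout cells and fell with PMCA4b. Among them were Dcn, Esm1, Mfap5, the transcription cofactor Lmcd1 (at least 9.62-fold up, then at least 8.20-fold down) and the small GTPase Rasl11b. Renbp, an enzyme of amino sugar metabolism, was at least 9.81-fold up and then 8.13-fold down. Tnfrsf11b, the decoy receptor osteoprotegerin, was at least 8.61-fold up and 7.99-fold down, but stood at 10.6 ± 0.0615 (SD, n = 5) with PMCA4b, above both wild type (6.02 ± 0.273, SD, n = 5) and knockout cells (9.52 ± 0.180, SD, n = 5). The others were the purine enzyme Xdh, the insulin signalling inhibitor Pid1 and the protease inhibitor Serpina3n (10.4-fold down). Of 3655 genes called in both comparisons, 2206 moved in opposite directions (1119 up and then down, 1087 down and then up) and 1449 in the same direction (Fisher's exact test two-sided, odds ratio 0.416, p = 1.365e-38). Independent lists of these sizes would share 825.6 and 916.1 genes in the opposed directions. The median log2 fold change with PMCA4b was -0.23 for the 2038 genes higher in knockout cells and 0.10 for the 2390 lower ones. Genes are not independent replicates, which the Fisher test assumes. Across genes the correlation of fold changes was weak, with Pearson's r = -0.135 and Spearman's rho = -0.165. Where both changes were at least 2-fold, 123 genes were opposed, 102 up and then down but 21 down and then up, and 76 were not, and at a fold minimum of 1.5 for both the opposed genes numbered 422. The comparisons share no arrays, and PMCA4b cells were compared with vector cells, not with the knockout cells themselves. Mitosis genes had a mean log2 of -0.721 for vector against knockout and 0.999 for PMCA4b against vector. Dcn read 9.805 in knockout cells, 12.53 with vector A, 13.02 with vector B and 8.355 with PMCA4b. For these genes, most of the change with PMCA4b offsets a change with vector. The same holds for the mean change of the cholesterol, fatty acid oxidation and immediate early lists. For knockout against wild type the mitosis genes had a mean log2 of -0.609, so with PMCA4b they stayed below wild type on average. Of 32 matrix genes, 9 rose and 19 fell with vector.

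**Figure D4:**
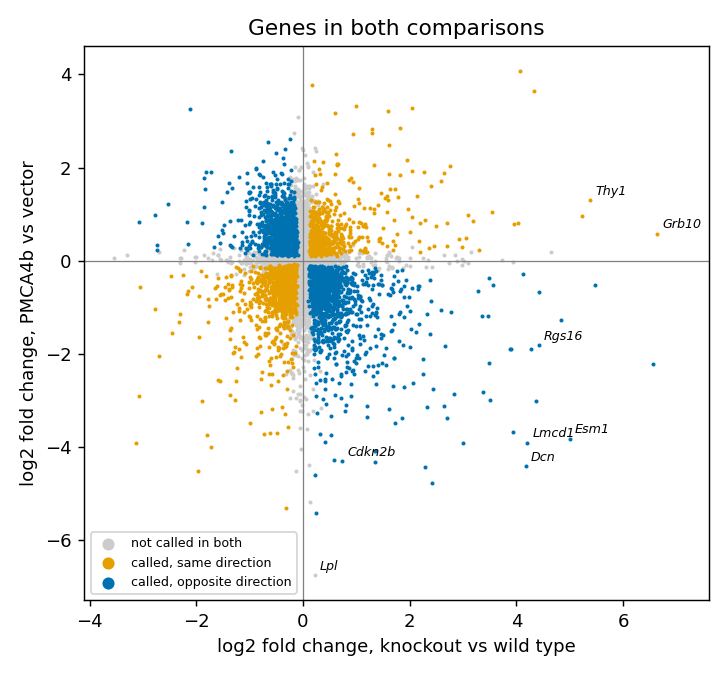
Each point is a gene, with its log2 fold change for knockout against wild type on the horizontal axis and for PMCA4b against vector on the vertical axis; colours mark genes called in both comparisons. The 2206 genes of opposite direction lie in the upper left and lower right, and the 1449 of the same direction in the other quadrants.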

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

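Tests chosen only after the result was seen were both tests of the vector groups, the test of the share of smooth muscle cells and both tests of Cdkn2b. Among the genes named here, 290 groups of 4 or 5 arrays were searched for an array far from the others of its group. It stood out in 11 of them (3.79%), about the 1 in 20 that chance gives.

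In knockout cells, Gvin1 read 5.88 in replicate 5 (nearest other array 5.625), Acta2 16.016 in replicate 2 (15.95), Col4a2 11.18 in replicate 1 (11.36), Rcan2 10.35 in replicate 3 (10.19) and Hmgcs1 13.99 in replicate 1 (13.85). In wild type, Mustn1 read 8.159 in replicate 4 (8.351). With vector A, replicate 4 stood apart for Atp2b4 at 6.407 (6.693) and for Akr1c12 at 5.061 (4.891). With vector B, Mybl2 read 8.895 in replicate 3 (8.662). With PMCA4b, Xdh read 5.744 in replicate 4 (6.595) and Egfl7 9.358 in replicate 1 (9.263). All values are normalized log2 intensities.

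PMCA4b cells differed from vector A and from vector B in opposite directions at 177 genes for which the difference between the vectors was itself called by limma. Dlk1 was lower than with vector A (log2 -1.23) and at least 3.62-fold higher than with vector B, where it was undetected. Plvap and Tril were at least 1.52-fold and 5.86-fold higher than with vector A, where they were undetected, and lower than with vector B (log2 -2.08 and -0.89). Probes without a gene name, which no comparison uses, also held calls, at no more than the share over all genes. Of 635 such probes, 338 were called for knockout against wild type (53.2%, against 57.7% of genes), 476 for PMCA4b against vector (75% against 78.8%), 307 for vector B against vector A (48.3% against 53.4%) and 468 for vector against knockout (73.7% against 74.4%).

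Vector B and vector A differ at 238 genes by at least 2-fold, Tril, Plvap and Dlk1 among them. Vector A lies in a single column set with the lowest median intensities (21.82 to 24.3, against 25.65 to 29.58). With the set as a block 236 of the 238 genes were still called and 196 still differed at least 2-fold. For these genes, this argues against the set as the whole cause. Of all 4099 called genes, 2786 were also called with the block, so smaller differences are less certain. The block for that set rests on the 3 arrays of other groups in it, whose deviations correlated with each other (r from 0.42 to 0.47). Because 0 of the column sets hold both vectors, separate cultures or electroporations may explain the difference and cannot be told apart from the DNA used. No biological explanation was tested, as the labels do not say how the vectors differ.

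Knockout and wild-type cells differ in part in ways that cells given PMCA4b DNA share with the knockout, as for Inmt and Gdnf. That these cells expressed the pump is not shown by the Atp2b4 probe. DNA of another strain around the targeted gene could add to this. Of the 40 measured genes nearest to Atp2b4, 9 separated wild type from all knockout-derived arrays, against 5.62 expected (one-sided Fisher's exact p = 0.101), which leaves it open. A lower share of smooth muscle cells in the knockout cultures would lower contractile genes, of which 11 rose and 0 fell. These genes may also change within cells, and with vector against knockout 10 of 14 fell and 2 rose. They therefore do not settle the share of cells. Fibroblast markers rose as well (6 of 9 higher and 1 lower, camera adjusted p = 2.56e-05), so a change in the make-up of the cultures stays open. Differences between single cultures stay open, since 35.5% of the 510 genes that differed at least 2-fold lay nearer to wild type in vector cells, which received no PMCA4b DNA, and 45.5% with PMCA4b, as does the loss of PMCA4 itself.

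Cdkn2b was detected on 0 of 5 PMCA4b arrays. The column set is argued against, because 19 of 19 arrays of other groups, spread over all 3 sets, detected it. Of its expressed neighbours, Cdkn2a was detected on 0 of 5 PMCA4b arrays, with its probes at 5.96 ± 0.323 (SD, n = 5) and 4.955 ± 0.229 (SD, n = 5), while Mtap was detected on 5 of 5 at 11.2 ± 0.0983 (SD, n = 5). Loss of the DNA that holds Cdkn2b and Cdkn2a in these cultures is a candidate explanation, and joint silencing would look the same. A test of these cultures' DNA would decide. Whether the missing inhibitors account for the rise of cell division genes was not tested. The other groups point both ways. Cdkn2b was higher in knockout cells (11.12) than in wild type (10.38) where 29 of 31 mitosis genes fell, and lower in vector B (8.619) than in vector A (9.946) where 29 of 31 were higher, but it was also lower in both vector groups than in knockout cells, where 29 of 31 fell with vector.

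Other splits of the arrays tested whether chance could give as many calls, with 100 splits each and fits on the groups compared alone. For called genes, 1 of 100 splits, the real one, reached the real count in each of the 6 comparisons of groups. Other groupings of these arrays thus did not give as many calls. Where replicates are repeats of a single culture, any difference between cultures would give this result, so such differences are not excluded. The real count and the highest of the other splits were 4108 and 1 for knockout against wild type, 6110 and 2553 for PMCA4b against vector, 6105 and 0 against vector A, and 5432 and 3771 against vector B. They were 4379 and 2078 for vector B against vector A and 5801 and 3408 for vector against knockout. For opposed genes 1 of 100 joint splits, the real one, reached the real count of 2070 (highest other 0). Other splits of knockout and wild-type arrays call at most 1 gene, so this shows that the calls exceed those of other splits and says nothing about their directions.

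For called lists, 1 of 100 splits, the real one, gave as many for PMCA4b against vector (real 9, highest other 7). The same held against vector B (8 and 7), and both margins are small. Other splits gave as many for knockout against wild type (7 of 100, real 7, highest other 8) and PMCA4b against vector A (10 of 100, 7 and 8). So did those for vector B against vector A (32 of 100, 4 and 5) and vector against knockout (9 of 100, 5 and 6). Other splits still mix the real groups, mostly in unequal shares, so part of a real difference can remain in them. The number of called lists also does not say which lists were called. For these 4 comparisons the splits therefore neither exclude chance nor speak against single list calls.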

How the results depend on the processing

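The column set as a block, fits within column sets, and the fit without the 3 arrays of the third set outside vector A were chosen after seeing the data. The counts of called genes stayed within 1.5 times under all alternatives except those given here, and no scaling moved the share of higher calls by over 10 percentage points. With a fold of at least 1.5 required, the counts were 1259 for knockout against wild type, 2825 for PMCA4b against vector, 3297 against vector A, 2567 against vector B, 912 for vector B against vector A, 2301 for vector against knockout and 422 for opposed genes, by construction. Within single column sets, with fewer arrays, 2743, 2790 and 2216 genes were called for knockout against wild type. In the third set each of these groups has 1 array, assumed to vary like vector A, the only group with replicates there and the one with the smallest median SD (0.0955, against 0.123 in wild type and 0.118 in knockout), so 2216 may be too high.

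Fry, which asks only whether a list moves on balance in 1 direction, called 18, 17, 17, 17, 14 and 18 of 18 lists in these comparisons. With the authors' values 4445 and 6055 genes were called for knockout against wild type and PMCA4b against vector.

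Atp2b4 changed sign under several alternatives. It was called under the column set as a block alone, where it was lower with PMCA4b than with vector A and lower in vector B than in vector A. Its log2 difference of PMCA4b from vector B was -0.01672 without background correction. With median scaling it was -0.0315 from vector, -0.008943 from vector A and -0.05406 from vector B. The cause was not tested. Where probes detected on all arrays were required, Atp2b4 was not tested. Among the 243 values of named genes, reversals occurred for Atp2b4 alone. Calls were lost under some alternatives for Plin4 in knockout against wild type, and for Cd14, Krt19 and Rgs3 in PMCA4b against vector. Krt19 lost its call with the authors' values (limma adjusted p = 0.119) and Rgs3 with averaged probes (0.0678).

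With the replicate number as a block, Atp2b4 of vector B against vector A was -0.03813. The calls of immediate early genes and of ribosomal proteins for PMCA4b against vector A were lost with this block (camera adjusted p = 0.0501 for both). Over the camera alternatives these ranged from 0.00877 to 0.0501 and from 0.00825 to 0.0561. Arrays of equal number shared little: their deviations had mean correlations of 0.025 to 0.0567 for numbers 1 to 4 and 0.259 for number 5, whose arrays all share a column set, though 15 of 24 arrays correlated best with one of their own number. With the column set as a block it was -0.1384 for PMCA4b against vector, -0.391 against vector A (adjusted p = 0.046; from 0.046 to 0.96 over its alternatives), -0.5051 for vector B against vector A (adjusted p = 0.0444; from 0.0444 to 0.902) and 0.02496 for vector against knockout, and vector A lies in no other set. The cause was not tested.

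In leave-one-out fits, without 1 array each, there were 4230 to 4306 called genes for knockout against wild type, 5895 to 6018 for PMCA4b against vector, 5940 to 6031 against vector A, 5351 to 5488 against vector B, 3757 to 3903 for vector B against vector A, 5534 to 5657 for vector against knockout and 2105 to 2212 opposed genes. Atp2b4 ranged from -0.03139 to 0.1145 for knockout against wild type, -0.1098 to 0.2377 for PMCA4b against vector, -0.08825 to 0.2593 against vector A, -0.1314 to 0.2161 against vector B and -0.04804 to 0.134 for vector B against vector A.

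Signal over background limits the dim genes. Of 25697 probes, 13667 were detected on no array, and 82 called genes of knockout against wild type were detected on neither side.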

Other observations

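No test in this part was chosen only after its result was seen. Lpl, Plin4 and Pparg, markers of adipocytes, were the measured members of a list too short to test. Lpl read 7.458 ± 0.105 (SD, n = 5) in wild type, 7.675 ± 0.297 (SD, n = 5) in knockout cells, 11.2 ± 0.0613 (SD, n = 5) with vector A and 12.39 ± 0.0679 (SD, n = 4) with vector B, and was undetected with PMCA4b. All 3 were higher with vector than in knockout cells and lower with PMCA4b than with vector.

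All 19 knockout-derived arrays lay above all 5 wild-type arrays at 496 genes and below them at 587, against 0.3611 expected if all 24 arrays were exchangeable. That value ignores the differences between cultures: PMCA4b arrays lay apart from all others at 1565 genes, vector A at 1586, knockout at 497 and vector B at 462, and the 1083 of wild type lie between these. The difference was at least 2-fold in each group for 94 and 75 genes. Dpt, Dcn and Tnfrsf11b were detected on every knockout-derived array and on no wild-type array, as were 24 genes in all.

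Detected on all arrays of 1 group and on none elsewhere were 28 genes in wild type (such as Inmt), 29 in knockout cells (such as Grb10), 9 with PMCA4b (such as Ctsw), 10 with vector A and 18 with vector B. Detected on all other arrays and on none of 1 group were 6 genes for knockout cells (Tnfrsf21, Deptor, Cxadr, Ank3, Sema6d and Tmem176a, all but Tnfrsf21 chosen after their values were seen), 54 for PMCA4b, 20 for vector A and 0 for vector B.

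A hypothesis was that cell cycle genes alone make up the opposed pattern. Without the genes of both cell cycle lists, 2146 of 3591 genes called in both comparisons moved in opposite directions, against 2206 of 3655 with them. The odds ratio without them was 0.437 (Fisher's exact test two-sided, p = 6.681e-34). The listed genes are thus not the whole pattern. They are too few for their removal to undo it, and cell cycle genes outside the lists stay in, so the hypothesis is not decided.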
